A study of Mus musculus with 8 samples.

How the data were processed

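RNA from 8 mouse liver samples was hybridised to Affymetrix Mouse Gene 1.0 ST arrays, which read each transcript with probes spread along its length and combine them into probe sets. Per the labels' protocols, RNA was purified on columns, and 150 ng was amplified, fragmented and labelled with biotin with the Ambion WT Expression kit. Per the submitters' processing notes, the authors used RMA, which corrects background, normalizes between arrays and summarises probes to probe sets. Its version and software are not given in the sources used here. The deposited values are log2 intensities with 2 decimals, as their range and near-equal medians show. No genome build is given in the sources used here.

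The table held 35556 probe sets. GEO's annotation of the array gave exactly 1 gene symbol to 21789 of them, several symbols to 1621 and none to 12146. Gene IDs of 21698 of the single-symbol probe sets were found in the RefSeq gene table of assembly GRCm38.p6, and 0 symbols needed an update. That table was also used to match the genes of the lists to gene IDs by symbol or synonym, and for each gene's chromosome and order along it. Each of the 19939 genes tested was represented by 1 probe set. Where a gene had more than 1, as for 998 genes, the probe set with the highest mean over all 8 arrays was taken. No gene was named from a probe set with several symbols, and no filter on dim probe sets was applied.

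The 4 Hmgb1 deleted and 4 floxed control arrays were compared per gene with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided, no covariate), and p-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Fold changes are deleted minus control on the log2 scale, with the standard error (SE) and 95% intervals of the moderated fit. Gene lists were tested with limma's camera, which asks whether a list's genes differ more than the other genes, with a preset inter-gene correlation of 0.01 and adjustment over 37 lists. Camera with the correlation estimated per list and fry, limma's rotation test of a list by itself, were run beside it. Adjusted p-values named below as list values come from camera unless another test is named. A list's mean per array was also compared by an exact 2-sided permutation test, which with 4 against 4 cannot give a p below 0.0286. Python 3.11.15 and matplotlib 3.10.9 were used for tables and figures.

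The test, the lists, the alternatives and the rule for naming genes were fixed before the data were examined. The lists covered autophagy, lysosome and mitochondrial genes, liver metabolic pathways, stress and immune responses, and markers of liver cell types. Of 1024 distinct list genes, 930 were measured, 33 lay only on probe sets of several genes and 61 had no probe set named here. The rule named Hmgb1, Hmgb2 and Hmgb3, then the 15 largest rises and the 15 largest falls among genes past the threshold whose 4 values in one group all lay above the 4 of the other. It left out predicted genes, microRNAs and olfactory or vomeronasal receptor genes. For each list described, up to 4 members with the smallest p were added.

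The scripts were tested on simulated arrays of this comparison with 19939 genes. They recovered 97.0% of 67 genes changed 1.5-fold, 100% of 67 genes changed 2-fold and 100% of 66 genes changed 3-fold, and 11 of 209 genes called were unchanged ones. In the same simulation 1 list was moved and 1 list was called. Its genes were drawn independently of each other, so it cannot show how often lists of genes that move together are called. Each gene had equal spread on all simulated arrays, unlike the real ones. The shares recovered therefore test the scripts and do not give the power of the real comparison. Alternatives covered a filter on dim genes, all probe sets, the mean of a gene's probe sets, quantile normalization applied again, centring of arrays on their medians, a variance trend, a robust prior variance (which camera has no option for, so the list tests there repeat the main ones), array weights, the replicate number as a block, each array left out in turn, and the estimated correlation. An estimated correlation without floxed control 1, and both arrays numbered 1 left out, were added after seeing the data. Arrays give no count of reads. Precision was limited by the number of arrays and the spread between them, with array weights from 0.25 (control 1) to 2.58 (control 4). Probe sets with several symbols or none were left out of the gene comparison and are described separately.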

Results

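Gene expression was measured in livers of male mice 8 weeks old. In 4 samples Hmgb1, which encodes an abundant DNA-binding protein of chromatin, had been deleted with Albumin-Cre, a recombinase driven by a promoter active in hepatocytes. The other 4 samples came from littermates that carried floxed Hmgb1 alleles. The sample titles name Cre in the deleted group only, so Cre itself and the loss of Hmgb1 cannot be told apart here. The labels are at odds on both tissue and strain. The protocol and source fields name whole liver and a C57Bl/6 background, whereas the characteristics name liver stellate cells and Balb/c. Albumin, a hepatocyte product, had log2 intensities of 13.26 to 14.03 on the 8 arrays. The labels do not state that each array is a separate animal, so p-values measure the spread between these arrays. Array medians lay between 6.08 and 6.22 on the log2 scale, and correlations between arrays between 0.983 and 0.996. Floxed control 1 stood apart from the rest, at 26.6 on the first principal component (37.6% of the variance) against −9.89 to −6.33 for the other controls and −11.7 to 11.4 for the deleted arrays.

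The deleted gene was compared first. Hmgb1 was lower in the deleted livers, at a log2 intensity of 4.60 ± 0.31 (SD, n = 4) against 5.50 ± 0.19 (SD, n = 4) on the probe set assigned to it alone, a log2 fold change of −0.91 (SE 0.14, limma adjusted p = 0.0216). This probe set was dim, with only 16.4% of the tested genes at a lower mean, and the filter on dim genes removed it. All 4 deleted arrays lay below all 4 controls. A further 34 probe sets were shared by Hmgb1 and its copies elsewhere in the genome, and 33 of these were lower with an adjusted p under 0.05 in the fit over all probe sets. Their log2 fold changes ran from −0.57 to −2.57 (1.48-fold to 5.92-fold lower), with a median of −2.15 (4.45-fold lower). The median over these sets was 7.21 ± 0.12 (SD, n = 4) on the deleted and 9.34 ± 0.15 (SD, n = 4) on the control arrays, with an exact permutation p of 0.0286, the smallest that 4 against 4 can give. The related Hmgb2 and Hmgb3 did not pass, with log2 fold changes of −0.012 (95% interval −0.19 to 0.16) and 0.095 (−0.11 to 0.30). Only the brightest of the 4 probe sets of Hmgb2 and of the 2 of Hmgb3 was used. That of Hmgb2 was dim, with means of 5.86 on deleted and 5.87 on control arrays, below all array medians. Hmgb3 ran from 0.048 without deleted 2 to 0.18 without deleted 3, and Hmgb2 changed sign to 0.0091 with quantile normalization again and 0.0075 with arrays centred on their medians. The single-gene set of Hmgb1 kept its direction but lost the call when all probe sets were tested (adjusted p = 0.0652) and without deleted 3 (0.073), deleted 4 (0.0687), control 3 (0.0561) or control 4 (0.0797). Which exons the probes cover relative to the floxed part is not given in the sources used here.

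**Figure D1:**
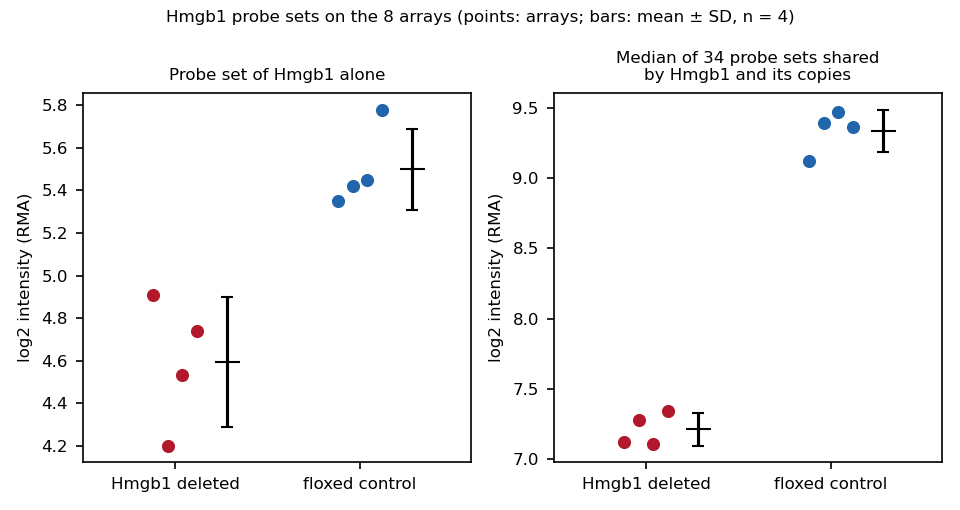
Log2 intensity of the Hmgb1 probe set (left) and the median of the 34 probe sets shared by Hmgb1 and its copies (right) in deleted (red) and control (blue) livers. Points are arrays and bars show the mean ± SD (n = 4); the deleted arrays lie below the controls in both panels, at 7.21 against 9.34 for the shared sets.

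The comparison then asked which other genes differed. Rgs16, a regulator of G protein signalling, fell by 2.35 on the log2 scale (SE 0.38, adjusted p = 0.0225), and Mme, the cell-surface peptidase neprilysin, fell by 2.17 (SE 0.17, adjusted p = 0.000658). Slc22a7, an organic anion transporter, fell by 1.48 and had the smallest adjusted p of all genes (SE 0.072, adjusted p = 1.14e-05). The complement regulator Susd4 fell by 1.78, the organic anion transporter Slco1a4 by 1.45, the amino acid transporter subunit Slc3a1 by 1.40, Nxpe2 by 1.21, the retinol dehydrogenase family member Rdh9 by 1.11, and Apcs, which encodes serum amyloid P, by 1.06. Nox4, an NADPH oxidase, Lipg, endothelial lipase, Slc17a8, a glutamate transporter, Rdh11, another retinol dehydrogenase, and Pxmp2, a peroxisomal membrane protein, fell by 0.93 to 0.99. The largest rises were those of Apoa4, an apolipoprotein, at 1.13 (SE 0.15, adjusted p = 0.00992), and of the interferon-induced Ifit1 at 1.09 (SE 0.16, adjusted p = 0.0130).

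Rises between 0.71 and 0.93 were found for Gabbr2, a GABA receptor subunit, Bdh2, Mgmt, which repairs alkylated DNA, Srebf1, a transcription factor of lipid synthesis, Rfxank, the interferon-induced Rsad2 and Cmpk2, Tubb2a, a tubulin, Gstt3, a glutathione transferase, Cers6, a ceramide synthase, Slc18a1, Trim14 and the kinase Fam20c. In all, 138 of 19939 genes passed the threshold, 59 higher and 79 lower in the deleted livers. Of these, 61 differed at least 1.5-fold (23 higher, 38 lower) and 11 at least 2-fold (2 higher, 9 lower). The groups did not overlap for any of the 138. Over all genes they did not overlap for 1111, or 5.57%, where chance gives 2.86%. The split moved with scaling, to 153 higher and 111 lower of 264 after quantile normalization again and to 33 higher and 28 lower of 61 with arrays centred on their medians. Single arrays moved the count too: it was 321 without control 1, 82 without control 2, 71 without control 3, 42 without control 4, 67 without deleted 2, 53 without deleted 3 and 37 without deleted 4. More genes were higher than lower without deleted 1 (59 and 39), deleted 3 (27 and 26), control 3 (37 and 34) or control 4 (26 and 16).

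**Figure D2:**
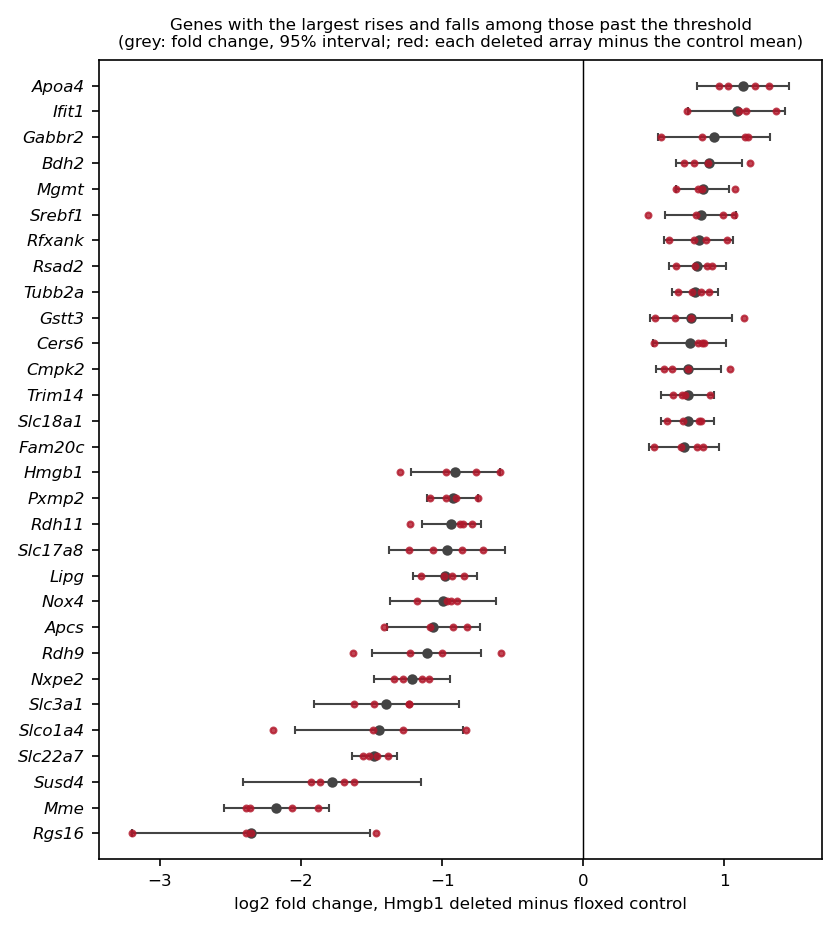
Log2 fold changes (deleted minus control) of the 15 largest rises and 15 largest falls among genes past the threshold. Grey points and bars are fold changes with 95% intervals and red points are single deleted arrays minus the control mean; Rgs16 has the largest fall, −2.35, and Apoa4 the largest rise, 1.13.

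The series title asks about autophagy and mitochondrial quality control. None of the 50 measured genes of the autophagy machinery passed the threshold over all genes (0 of 50, limma), with 28 higher, 21 lower and 1 equal. Adjusted over the list alone, 5 passed. Atg7, an E1-like enzyme of LC3 conjugation, had a log2 fold change of 0.35 (SE 0.078) and Atg2a, a lipid transfer protein, of 0.31, while the ubiquitin-like Gabarapl1 had −0.33 (SE 0.072) and Map1lc3b −0.30 (SE 0.068), and the WIPI protein Wdr45 had −0.22. The cargo receptor Sqstm1 had equal means. The mean log2 fold change of the list was −0.0060, its median 0.010, and its adjusted p 0.911 (0.973 with an estimated correlation). For change in either direction the list passed (fry, adjusted p = 0.0197), as did 20 of the 37 lists. The 95% intervals of 48 genes lay within 1.5-fold and those of all 50 within 2-fold.

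Of the 35 measured genes of mitochondrial quality control, 0 passed over all genes and 0 over the list alone, with 14 higher and 21 lower. Those with the smallest p were the mitofusins Mfn2 (0.24, SE 0.062) and Mfn1 (−0.20, SE 0.083), the mitophagy receptor Bnip3 (−0.18) and the inner membrane peptidase Oma1 (0.30). The list had a mean log2 fold change of −0.0026, an adjusted p of 0.911 (0.973 with an estimated correlation; 0.328 for change in either direction), and 34 of 35 intervals within 1.5-fold. Floxed control 1 lay below the other controls for both lists, and without it the means became −0.067 for autophagy (adjusted p = 0.0121) and −0.067 for mitochondrial quality control (adjusted p = 0.0165). With an estimated correlation neither passed there (adjusted p = 0.717 for each).

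**Figure D3:**
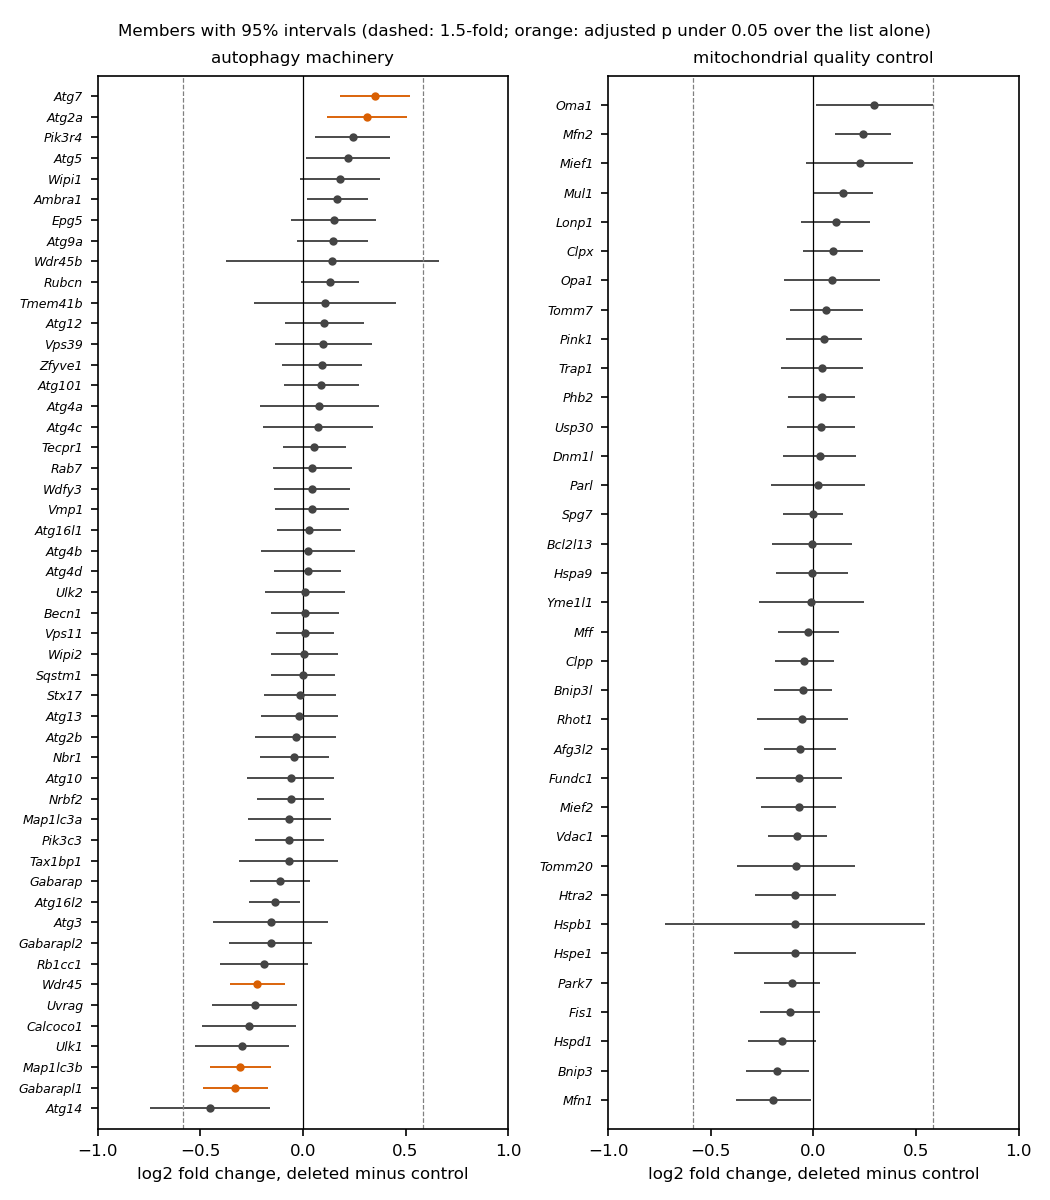
Log2 fold changes (deleted minus control) with 95% intervals of the measured autophagy (left) and mitochondrial quality control (right) genes. Dashed lines mark 1.5-fold and orange genes have an adjusted p under 0.05 over the list alone; 48 of 50 and 34 of 35 intervals lie within the dashed lines.

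Interferon response genes formed the 1 list that passed as higher in the deleted livers (adjusted p = 3.78e-17), a call lost with an estimated correlation (adjusted p = 0.424). Of 32 measured members 30 were higher, and 3 rose past the threshold over all genes, Ifit1, Rsad2 (0.81, SE 0.091) and Bst2 (0.65, SE 0.11), which restricts the release of viruses. Oasl1, at 0.55, did not pass over all genes. Adjusted over the list alone, 15 passed as higher and 1 as lower. The list's mean log2 fold change was 0.39 (exact permutation p = 0.0571 on array means). Deleted arrays had list means between −0.073 and 0.50 and controls between −0.39 and 0.0011, so the groups overlapped. Markers of T, B and NK cells (25 measured), macrophages (25) and neutrophils (16) held 0 genes past the threshold, with adjusted p of 0.921, 0.867 and 0.964.

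Lower lists included acute phase and complement genes, of which 28 of 30 were lower. Apcs fell past the threshold, and 9 genes passed over the list alone, among them the hepcidin gene Hamp (−0.34), Saa3 (−0.29) and Saa1 (−0.85). The list's mean was −0.29 (adjusted p = 3.29e-11, 0.424 with an estimated correlation), and floxed control 1 lay highest of all arrays. Cytochrome P450 and xenobiotic genes were lower for 37 of 48. Cyp2c55 fell by 0.72 (adjusted p = 0.0337), and Cyp1a2 (−0.29), Cyp2j5 (−0.26) and Cyp2d9 (−0.43) did not pass over all genes, with 7 genes passing over the list alone. That list had an adjusted p of 3.84e-05 (0.614 with an estimated correlation). Sex-biased and growth hormone-regulated genes were lower for 23 of 32, 0 of which passed over all genes and 5 over the list alone. Cyp7b1 had a log2 fold change of −0.95, Ghr, the growth hormone receptor, of −0.25 and Ugt2b1 of −0.30. The adjusted p was 4.48e-05 (0.424 with an estimated correlation).

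Genes of bile acid synthesis and transport were lower for 15 of 25. The hepatocyte uptake transporter Slco1b2 fell by 0.36 (adjusted p = 0.0367). Fgfr4, the receptor for FGF15 (−0.33), and Cyp8b1, the sterol 12-alpha-hydroxylase (−0.41), were lower and the exporter subunit Slc51b higher (0.47) without passing over all genes. Of the circadian clock genes 13 of 20 were lower. Per1 fell by 0.49 (adjusted p = 0.0226), and Ciart (−0.68), Bhlhe40 (−0.48) and Usp2 (−0.42) passed over the list alone, where 3 genes were higher and 7 lower. Amino acid catabolism and urea cycle genes were lower for 20 of 26. Tdo2, which opens the tryptophan ring, fell by 0.44 (adjusted p = 0.0345), Arg1 had −0.20 and Agxt −0.27, and Gpt had 0.24. Genes of respiratory chain complexes II to V were lower for 32 of 38 with 0 past the threshold, Uqcr10 at 0.23 and Atp5c1, Atp5h and Atp5pb between −0.22 and −0.19. The separate list of complex I genes, 21 of 34 of them lower, did not pass (adjusted p = 0.40, 0.0023 without control 1). Adjusted p was 0.0278 for bile acid, 0.0272 for clock, 0.0158 for amino acid and 0.00556 for complexes II to V genes, and with an estimated correlation 0.885, 0.614, 0.973 and 0.973. The lists of bile acid, amino acid and complexes II to V genes lost their calls after quantile normalization again, where the means of the last 2 were −0.00040 and −0.00020. For amino acid genes deleted 4 lay lowest, at −0.17 against −0.044 to 0.077 for the other deleted arrays. Without deleted 4 their mean was −0.030 and the call was lost (adjusted p = 0.267).

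Among cell types, markers of sinusoidal endothelial cells were lower for 23 of 24. Clec4g, a lectin of these cells, fell by 0.61 (SE 0.076, adjusted p = 0.00629), although not with the mean of its probe sets (adjusted p = 0.121). Lyve1 (−0.44), Oit3 (−0.21) and Fcgr2b (−0.20) did not pass over all genes, and 2 passed over the list alone. The list's mean was −0.18 (adjusted p = 1.25e-09, 0.424 with an estimated correlation). Hepatocyte markers were lower for 20 of 21 with 0 past the threshold, among them Ttr (−0.25), Itih2 (−0.19), Pck1 (−0.22) and Fgb (−0.17), and a mean of −0.11 (adjusted p = 0.00012, 0.916 with an estimated correlation). Deleted 4 had the lowest mean for these markers, −0.28 against −0.014 to 0.078 for the other deleted arrays, and an albumin value of 13.26 against 13.93 to 14.03 elsewhere. The highest log2 intensity of any probe set on deleted 4 was also low, 13.58 against 14.23 to 14.46 on the other arrays. Without deleted 4 the mean of the hepatocyte markers was −0.037 and the call was lost (adjusted p = 0.0856), as it was after quantile normalization again, where the mean was −0.0021. Pericentral hepatocyte markers were lower for 14 of 19 (mean −0.085, adjusted p = 0.0234, 0.614 with an estimated correlation; mean −0.028, adjusted p = 0.589 after quantile normalization again), with Cyp1a2 and Nr1i3 (−0.32) lower and Rhbg (0.35) and Lgr5 (0.31) higher, none past the threshold over all genes (0 of 19). Erythroid markers were lower for 7 of 11 (adjusted p = 0.0340, 0.424 with an estimated correlation), with Alas2, the heme synthesis enzyme of red cells, at −0.55, Car1 at −0.44, Car2 at −0.41 and Tfrc at 0.18, 0 of which passed over all genes.

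**Figure D4:**
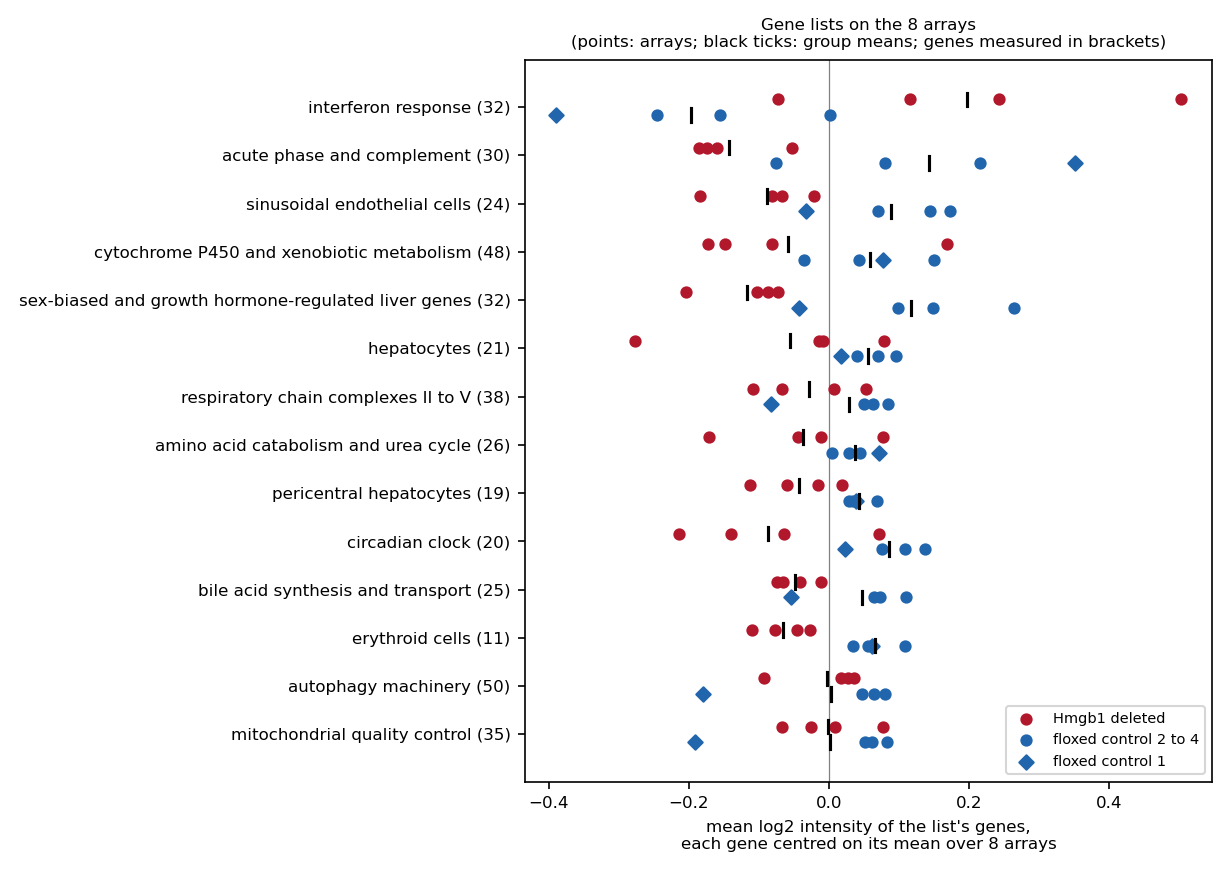
Mean log2 intensity per array of the 12 lists past the threshold and of the autophagy and mitochondrial quality control lists, each gene centred on its mean over the 8 arrays. Red points are deleted and blue points control arrays, with floxed control 1 as a diamond and group means as ticks; for interferon genes the deleted arrays lie between −0.073 and 0.50 and the controls between −0.39 and 0.0011.

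In total 12 of 37 lists passed with the preset correlation, 1 higher and 11 lower, and 0 with an estimated correlation, whose lowest p was 0.0117 before and 0.424 after adjustment. The exact permutation p on array means, not adjusted, was 0.0286 for sex-biased, pericentral and erythroid genes, the smallest possible. It was 0.0571 for interferon, acute phase, endothelial and clock genes and 0.0857 for bile acid genes. For P450, hepatocyte, amino acid and complexes II to V genes it was 0.229, 0.171, 0.2 and 0.286. Fry called 0 lists for a shift in one direction and 20, among them the autophagy list, for change in either direction. Of the 35 ways to split these 8 arrays into 4 and 4, 17 gave 12 or more lists. Only 1, the real split, gave as many as 138 genes.

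The 25 lists that did not pass had adjusted p between 0.257 and 0.964, and some held single genes that passed. In fatty acid synthesis (24 measured) Srebf1 rose by 0.83 (SE 0.11) and Lpin1, a phosphatidate phosphatase, fell by 0.62 (SE 0.12), while Fasn (0.76) and Me1 (−0.67) did not pass over all genes. In fatty acid oxidation (32 measured) Ppara, the nuclear receptor that controls it, fell by 0.49 (SE 0.088, adjusted p = 0.0367), with Vnn1 at 0.97 (0.63 without control 1, adjusted p = 0.00983), Pdk4 at 0.42 and Acadm at −0.21 not past the threshold. Of 32 lysosome genes only Asah1, acid ceramidase, passed, falling by 0.83 (SE 0.10, adjusted p = 0.00629), with Sgsh at 0.22, Ctsl at −0.21 and Ctsa at −0.19. For change in either direction the lysosome list had the lowest adjusted p of all lists (fry, 2.29e-07), in a test that 20 of the 37 lists passed. Mitochondrial biogenesis passed it too (fry, adjusted p = 0.000308). Of its 18 measured genes 0 passed over all genes, and 2 higher and 2 lower passed over the list alone. Of 28 oxidative stress genes only Gstm4 passed, falling by 0.54 (SE 0.099), with Keap1 at 0.25, Mgst3 at 0.29 and Gstm2 at −0.18. Among chromatin proteins (22 measured) Hmgb1 alone passed, with H1f2 at 0.46, Hmgn2 at 0.22 and H2ax at 0.18.

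Of the 39 genes named above that passed, other than Hmgb1, 15 passed in every alternative that gave them a value: Apoa4, Bdh2, Mgmt, Rfxank, Rsad2, Tubb2a, Slc18a1, Trim14, Mme, Slc22a7, Nxpe2, Lipg, Rdh11, Pxmp2 and Asah1. The other 24 lost the call in at least 1 alternative, with adjusted p of up to 0.180 for Slc17a8, and 0 of the 39 changed sign. Among named genes that did not pass, besides Hmgb2 and Hmgb3, single arrays moved some fold changes by more than 1.5 times. Without control 1, besides Vnn1, H1f2 had 0.285, Usp2 −0.27 and Oma1 0.16. Without deleted 1 H2ax had 0.12, Mfn1 −0.13 and Tfrc 0.29, without deleted 2 Cyp7b1 −0.62, and without deleted 3 Atp5h and Atp5pb −0.12. Without deleted 4 Fgb had −0.094 and Tfrc 0.11, and without control 2 Tfrc 0.11.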

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

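A value was singled out when 1 array lay far from the other 3 of its group, by the gap to its nearest neighbour over the group's range. In 248 groups of 4 values tested, 14 such values were found, where chance gives about 1 in 20, or 12.4. Of these, 11 fell on floxed control 1, 2 on deleted 1 and 1 on deleted 3. No explanation was tested for them.

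On floxed control 1, Nox4 had a log2 intensity of 7.67 against 8.50 to 8.51 on the other controls, Nxpe2 9.03 against 9.56 to 9.59, Me1 9.97 against 10.61 to 10.70 and Gstm4 10.81 against 11.22 to 11.28. Cyp2j5 was at 12.22 against 12.34 to 12.36, Itih2 at 12.29 against 12.38 to 12.39, Uqcr10 at 9.64 against 9.90 to 9.93 and Atp5pb at 10.66 against 10.92 to 10.97. For Nox4, Nxpe2, Me1, Gstm4, Cyp2j5, Itih2 and Atp5pb, all of which were lower in the deleted group, control 1 lay on the side of the deleted arrays. The mean of the autophagy list on this array was −0.18 against 0.047 to 0.081 on the other controls, and that of the mitochondrial quality control list −0.19 against 0.052 to 0.083. Its first principal component was 26.6 against −9.89 to −6.33.

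Deleted 1 lay below the other deleted arrays for Cers6, at 8.35 against 8.66 to 8.70, and for the mean of the autophagy list, at −0.092 against 0.017 to 0.036. Deleted 3 lay below them for Atp5pb, at 10.35 against 10.73 to 10.79.

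Probe sets without exactly 1 gene symbol were outside the gene comparison. When all 35556 probe sets were tested, 47 of these differed past the threshold. They comprised 33 of the sets shared by Hmgb1 and its copies, 5 other sets of several genes and 9 with no symbol listed, of which 6 were higher and 3 lower in the deleted livers.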

How the results depend on the processing

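Signal over background was not measured here. All settings were chosen before the data were examined except the estimated correlation without floxed control 1 and the fit without both arrays numbered 1. The cause of the differences below was not tested. The 138 genes past the threshold became 57 (34 higher, 23 lower) with all probe sets, 264 with quantile normalization again, 61 with arrays centred on their medians, 526 with array weights (138 shared), 366 without both arrays numbered 1 (132 shared), and 37 (without deleted 4) to 321 (without control 1, 90 higher and 231 lower, 138 shared) with 1 array left out, more of them higher than lower without deleted 1 (59 and 39) or 3 or control 3 or 4. Of 39 named genes past the threshold besides Hmgb1, 15 passed in every alternative and 0 changed sign.

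Whether the shared numbers 1 to 4 pair the arrays stays open: deviations of same-numbered arrays correlated at 0.447, 0.0652, −0.0814 and 0.422. For numbers 1 and 4 the deleted array correlated best with the control of its own number, for 2 and 3 it did not. With the replicate number as a block, 325 genes passed (162 higher, 163 lower) and the bile acid list lost its call (adjusted p = 0.0629).

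The Hmgb1 log2 fold change stayed at −0.905 with all probe sets, without the call (adjusted p = 0.0652), and lay between −1.01 and −0.773 with 1 array left out, without the call when that was deleted 3 or 4 or control 3 or 4 (0.0561 to 0.0797). The filter on dim genes removed Hmgb1 and gave no value. Hmgb2 changed sign to 0.0091 with quantile normalization again and 0.0075 with centred arrays, ran from −0.0667 to 0.0433 with 1 array left out, and was called in none of these settings.

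The 12 lists became 7 with quantile normalization again, 0 with an estimated correlation, 0 with it and without control 1, and 7 (without deleted 1 or deleted 4) to 14 (without control 1 or control 2) with 1 array left out. In every alternative with the preset correlation 5 lists passed: interferon, acute phase, endothelial, P450 and sex-biased genes. With all arrays kept, calls were lost for hepatocytes, respiratory, amino acid, pericentral and bile acid genes with quantile normalization again, pericentral, clock, bile acid and erythroid genes with all probe sets, and amino acid and erythroid genes with array weights, as without both arrays numbered 1 (there pericentral genes too). With 1 array left out, calls were lost without deleted 4 for hepatocytes, and without deleted 3 or control 3 for respiratory genes (adjusted p = 0.198, 0.148). They were lost without deleted 1, deleted 4 or control 1 for amino acid (0.0743 to 0.267) and erythroid genes (0.0889 to 0.101), and without deleted 1, deleted 4 or control 4 for pericentral genes (0.0679 to 0.0889). Clock genes lost the call without deleted 1 or 2 or control 3 or 4 (0.066 to 0.163), bile acid genes without deleted 1, 3 or 4 or control 3 or 4 (0.0682 to 0.191). Of the 25 other lists 7 passed in some alternative, 4 of them without control 1.

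The mean of the autophagy machinery list, near 0, turned to 0.0077 with quantile normalization again and 0.014 with centred arrays, and ran from −0.0669 (called, without control 1) to 0.0238 with 1 array left out. For the mitochondrial quality control list it turned to 0.0166 and 0.0174, and ran from −0.0668 (called, without control 1) to 0.0247.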

Other observations

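Of the tests in this part, those of the number of genes and lists under other splits of the arrays and of the clock phase were fixed before their results were seen. The tests of chromosome 3, the interferon genes and fasting were chosen after.

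Several further genes, picked after their values were seen, passed the threshold. Lpl, lipoprotein lipase, fell by 0.85 (SE 0.16, adjusted p = 0.0474), Abcd2, a peroxisomal transporter of very long chain fatty acids, by 0.89, and Erbb4, a receptor tyrosine kinase, by 0.81 (SE 0.098, adjusted p = 0.00629). The metalloreductase Steap2 fell by 0.83, the ferritin receptor Scara5 by 0.815 and Gsdmd, the pore-forming protein of pyroptosis, by 0.575. The tyrosine kinase Src rose by 0.46, the integrin subunit Itga5 by 0.57 and the Hedgehog signal transducer Smo by 0.56. The metallothioneins Mt1 (−1.21) and Mt2 (−1.63), which passed over the acute phase list alone, did not pass over all genes.

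Only 1 of the 35 splits of the 8 arrays into 4 and 4, the real one, gave as many as 138 genes, and the highest count among the others was 1, so the tables argue against a chance division of the arrays for the number of genes. For the 12 lists such a division stays open: 17 of the 35 splits gave as many, and the highest count, 24, came from the split that put floxed control 1 with deleted 1, 3 and 4. The counts of lists may therefore reflect differences between arrays other than the deletion.

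Chromosome 3 held 16 of the 138 genes, 11 lower and 5 higher, where 6.51 were expected from its share of the tested genes. Mme, Tdo2, Pdgfc, Smad9, Gstm4 and Gstm5 were among the lower and Bdh2, Prune1, Ampd2 and Cks1b among the higher. The tables argue against placement by chance, with a p over all chromosomes of 0.011 in 100000 random placements, which take genes as independent, and against neighbouring genes of one family, since 15 calls stayed with 1 gene per family where the 95% range of chance ends at 12. A chromosome segment of another strain carried in one group may account for it and stays open: the densest stretch of 235 of its 943 tested genes held 8 of the 16, against a median of 7 in random placements (permutation p = 0.336), and the labels name both C57Bl/6 after backcrossing and Balb/c. Without floxed control 1 the chromosome held 31 calls where 15.2 were expected, and with array weights 38 where 24.9 were expected.

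Interferon response genes were higher in the deleted livers by a mean of 0.39 (SE 0.15 over arrays), with an adjusted p of 0.424 for the list under an estimated correlation. The tables argue against a single array, as the mean was 0.29 at its lowest, without deleted 3, and against more macrophages in the deleted livers, whose 25 markers, 20 of them at or above the median level of the tested genes, had a median log2 difference of 0.005 (SD of markers 0.15) where added cells would need about 0.39. More T, B or NK cells or neutrophils in the deleted livers cannot be told apart: their 41 markers had a median of 0.0025 (SD 0.083), but 36 of them lay below the median level of the tested genes. Spread between animals of genes that move together may account for it and stays open, with an exact permutation p of 0.0571 on array means, as does an effect of the deletion.

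Some genes of the clock and of feeding had lower means in the deleted livers, Per1 and Lpin1 past the threshold and Bcl6 (−1.28, SE 0.41) and Ppargc1a (−0.82, SE 0.21) not. Of 20 clock genes only Per1 passed over all genes, while 3 higher and 7 lower passed over the list alone. The adjusted p of the clock list, 0.0272, became 0.614 with an estimated correlation. For change in either direction the list passed (fry, adjusted p = 0.00187), as did 20 of the 37 lists. A different clock phase at collection stays open. The mean log2 difference of Arntl, Clock and Cry1 minus that of Hlf and Per3 was 0.040 (SE 0.083, exact permutation p = 0.6), which does not decide it. Longer fasting of the controls stays open as well, since 27 genes that fasting raises in liver had a mean log2 difference of −0.16 (SE 0.087, exact permutation p = 0.114) and 17 of them were lower. Without the 4 genes already seen to be lower the mean was −0.046 (SE 0.087, exact permutation p = 0.571).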
